A study of Homo sapiens with 14 samples.

How the data were processed

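The 14 deposited tables hold 60587 genes each, with effective length, expected count and TPM per gene. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to GRCh38 and counted with RSEM 1.2.25, and libraries were made with the TruSeq RNA Library Prep Kit v2 after RNeasy micro extraction. The annotation release is not given in the sources used here. This kit does not mark the strand, so reads of overlapping antisense genes cannot be told apart.

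Per the file headers, the unit of the main test was the expected count, which was rounded to whole numbers. Per the file headers, TPM was used in the alternatives, after log2 of TPM plus 1 or plus 0.1. CPM values were computed from the deposited expected counts. The log2 fold changes were fitted to the deposited expected counts and are not values from the authors. The effective length was not used here.

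Of the gene identifiers, 60333 had a symbol and 58400 were found in GENCODE 29, which gave coordinates, transcript length and GC content. Genes were kept by filterByExpr with the 3 days as groups, which left 17838. Libraries were scaled by TMM. Dispersions were estimated with robust fitting, and 1 model with a mean per day over all 14 libraries was tested with the quasi-likelihood F-test of edgeR. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, in each comparison apart. The contrasts were day 30 against day 21, day 45 against day 30, day 45 against day 21, and the later change minus the earlier change. The SE of a log2 fold change is its value divided by the square root of F. Genes called with more than 2-fold change were counted from the fitted value, with no test against that bound outside the alternative with glmTreat.

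Samples, comparisons, the main test, the gene lists, the anchor genes and most alternatives were chosen before the data were examined. The length and GC offset, leaving out day 30 replicates 3 to 5, and thinning were added later.

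The library titled day 45 replicate 1 was used at day 45. Its treatment label reads 30 days, and leaving it out or placing it at day 30 were alternatives. Same-numbered libraries of different days were no more alike than others, with correlations of -0.25 to 0.12 in 13 pairs, so replicate numbers were not used to pair samples.

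The 38 gene lists were fixed in advance: cartilage matrix, chondrocyte transcription factors, hypertrophic cartilage, superficial zone and joint, bone matrix, phosphate handling, glycosaminoglycan synthesis, collagen processing, matrix proteases, fibrous tissue, tendon, skeletal, smooth and cardiac muscle, neuron, Schwann cell, melanocyte, epithelium, endothelium, blood, pluripotent stem cell, adipocyte, liver, cell cycle, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, interferon response, inflammatory response, p53 response, immediate early genes, BMP, TGF-beta and WNT targets, Hedgehog pathway, HOX genes, mitochondrially encoded transcripts and ribosomal proteins. Lists with at least 3 members tested were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with a correlation estimated per list and with fry. No member of the HOX list passed the filter, and the mitochondrially encoded list was not analysed here.

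Genes were named by rule. The 12 anchors were COL2A1, ACAN, SOX9, COL10A1, IHH, RUNX2, MMP13, SPP1, IBSP, PRG4, COL1A1 and MKI67. To these were added the 8 largest positive and 8 largest negative log2 fold changes per comparison of days and the 5 largest of each sign for the later minus the earlier change. Such genes had an adjusted p below 0.05, a mean of at least 10 CPM in the higher group or highest day, and a symbol that is not a clone name. In the comparisons of days alone, libraries of the days compared also had no overlap. Up to 4 members per list with the smallest adjusted p were added. A gene chosen in 1 comparison could be described in another. Some genes that the rule names are not reported here. Genes named otherwise are said to have been chosen after their values were seen.

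Separation of the days was measured as a pseudo-F on Euclidean distances of log2 CPM (prior count 2) over the 500 most variable genes, with 100000 permutations of the labels. Principal components used the same genes. For genes with few counts at 1 day, the ratio of summed counts per effective library size has an exact conditional interval. It covers counting error only, since PCR copies cannot be removed without molecular identifiers, and the spread between libraries is wider.

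Alternatives were DESeq2 size factors in edgeR, DESeq2 itself, limma on both TPM scales, limma voom with sample weights, no low-count filter, a filter of 1 CPM in 4 libraries, fits without robust dispersions, fits of only the days compared, a replicate block, glmTreat at 1.5-fold, leaving out each library in turn, and those for the label conflict. The offset was fitted per library as splines (4 degrees of freedom) of transcript length and GC content. Thinning brought all libraries down to the smallest total.

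In simulated counts with planted changes, edgeR recovered 30.8%, 66.2% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold between day 21 and day 30, with 15 false calls. For day 45 against day 30 it recovered 35.4%, 72.3% and 90.9%, with 3 false calls, and with no planted change between day 45 and day 21 it called 0 genes. For the second interval it recovered 47.7%, 78.5% and 95.5%, with 10 false calls. Camera called the 1 planted list and 0 others. A planted trend with transcript length gave 3997 calls without the offset and 0 with it. The planted trend was of the form that the offset fits. Genes were simulated as independent, and only a small share of them was changed. In the data the cell cycle list had an estimated correlation of 0.661 for day 30 against day 21, and most genes were called. These simulations therefore do not show how camera fares with correlated genes or edgeR with wide changes.

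Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.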

Results

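Cartilage pellets were grown from WA01, a human embryonic stem cell line also known as H1, in medium that turns the cells into chondrocytes. RNA from whole pellets was sequenced after 21 days (4 libraries), 30 days (5 libraries) and 45 days (5 libraries). The question was how the transcriptome of the pellets differs between these stages of cartilage formation. The libraries held 18183776 to 33660704 expected counts, with the fewest in a day 30 library. After the filter on low counts, 17838 genes were tested. Levels are CPM after TMM normalisation, and changes are log2 fold changes with their standard error (SE).

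A few matrix genes made up a larger part of the libraries at day 45 than at day 21. COL2A1, the gene of the main collagen of cartilage, made up 3.8% ± 0.338 of all counts at day 21 (SD, n = 4), 11.8% ± 3.07 at day 30 (SD, n = 5) and 13.8% ± 2.35 at day 45 (SD, n = 5). Its share was 13.3% to 14.6% in day 30 replicates 1 to 3, and 10.1% and 7.26% in replicates 4 and 5. It was 17.8% in day 45 replicate 1 and 12% to 13.6% in the others, so the shares of days 30 and 45 overlapped. ACAN, the gene of the large cartilage proteoglycan aggrecan, made up 0.388% ± 0.0821 (SD, n = 4), 1.68% ± 0.642 (SD, n = 5) and 3.11% ± 0.192 (SD, n = 5). FN1, the gene of fibronectin, was chosen after its values were seen and made up 1.63% ± 0.115 (SD, n = 4), 1.94% ± 0.478 (SD, n = 5) and 6.77% ± 0.617 (SD, n = 5). The 10 most abundant genes of a library held 13.3% to 14.04% of its counts at day 21, 18.93% to 29.25% at day 30 and 27.63% to 35.22% at day 45.

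Libraries of the same day lay closer to each other than to those of other days. The pseudo-F of the distances over the 500 most variable genes was 20.3 (permutation test with 100000 draws, p = 2e-05). The first principal component (58.1% of the variance) ordered the days, with day 21 at -46.4 to -42.9, day 30 at -9 to 0.4 and day 45 at 33.9 to 44.2. On the second component (22.2%) all day 30 libraries were negative, at -35.5 to -13, and the libraries of the other days lay at 10.7 to 23.4. The library titled day 45 replicate 1 carries 30 days in its treatment label. It lay at 44.2 on the first component, at the far end of the day 45 libraries, and was grouped by its title. No pair of replicates differed by as little as sampling noise, with a chi-square per degree of freedom of 8.64 to 198.15, and each library was counted once. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

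**Figure D1:**
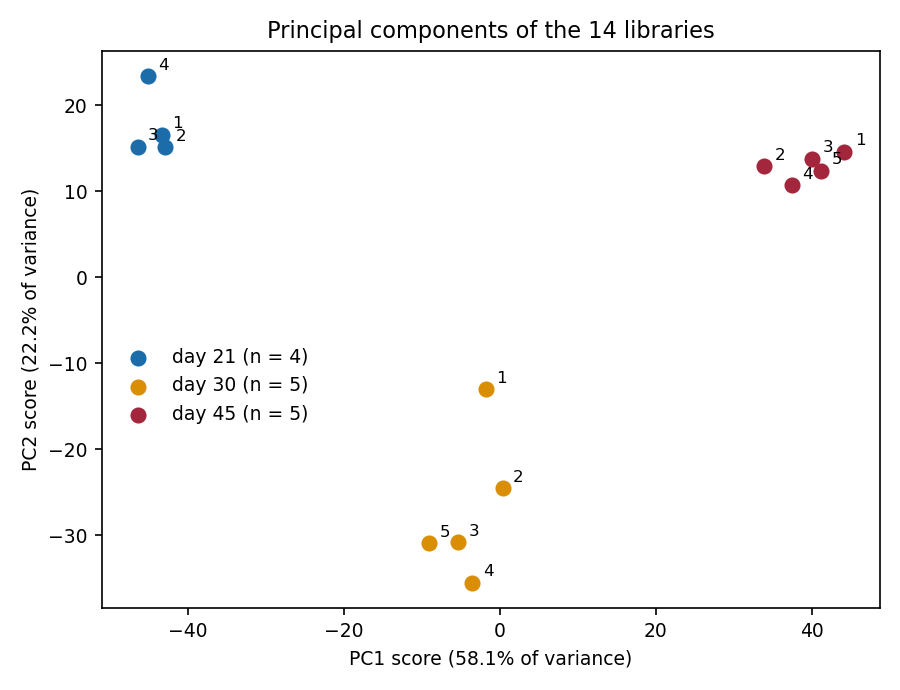
Each point is 1 library, placed on the first (58.1% of the variance) and second (22.2%) principal components of log2 CPM over the 500 most variable genes, and coloured by day. The days separate along the first axis, and the 5 day 30 libraries lie below the others on the second.

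Day 30 replicates 3, 4 and 5 stood apart from replicates 1 and 2. Across genes, which are not independent replicates, the deviation of a library from the mean correlated with transcript length at Spearman rho of -0.42, -0.47 and -0.43 in these 3 libraries, -0.04 and -0.07 in replicates 1 and 2, and 0.1 to 0.22 at the other days. MTCO1P12, a nuclear copy of a mitochondrial gene chosen after its values were seen, reached 7008.5, 12003.8 and 13649.5 CPM in the same libraries and 2772.9 to 5613.1 CPM in the others. As a copy it shares sequence with that gene, so which of the 2 these reads came from is uncertain. In the comparison of day 30 with day 21, the median change went from 0.39 in the shortest of 5 equal groups of genes by transcript length to -0.38 in the longest. Between day 21 and day 45 the same medians were -0.04 and -0.06, and this comparison is given first.

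**Figure D2:**
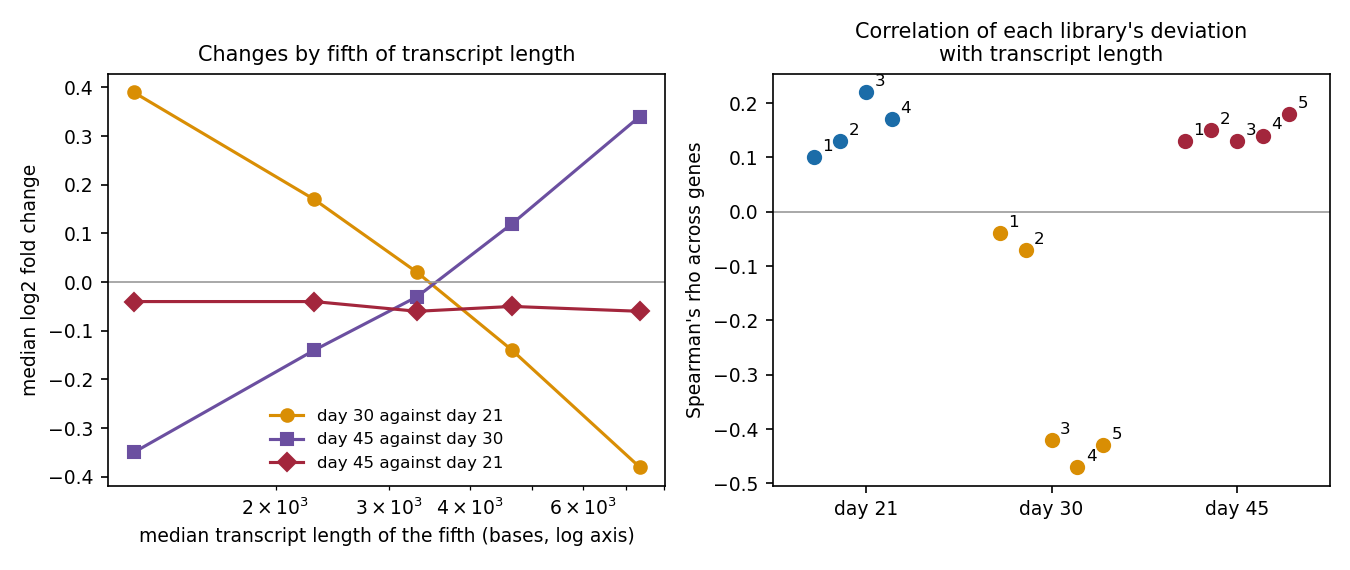
The left panel shows the median log2 fold change of genes in 5 equal groups by transcript length (median length 1205 to 7336 bases) for the 3 comparisons of days, and the right panel shows the Spearman rho between transcript length and the deviation of each library, 1 point per library. The medians run from 0.39 to -0.38 for day 30 against day 21 and from -0.04 to -0.06 for day 45 against day 21, and day 30 replicates 3 to 5 have the lowest rho.

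From day 21 to day 45 camera called the lists of cartilage matrix and hypertrophic cartilage upwards, and those of cell cycle, tendon and pluripotent stem cells downwards. With an estimated correlation none of them was called (adjusted p = 0.396, 0.0541, 0.261, 0.122 and 0.122). COL2A1 (ENSG00000139219; chromosome 12, 47972965 to 48004554, minus strand, GRCh38) rose 5.59-fold, from 29900 ± 3500 CPM (SD, n = 4) to 167100 ± 40300 CPM (SD, n = 5). ACAN (ENSG00000157766; chromosome 15, 88803442 to 88875354, plus strand) rose 12.2-fold, from 3060 ± 710 CPM (SD, n = 4) to 37350 ± 4120 CPM (SD, n = 5). COL10A1 (ENSG00000123500; chromosome 6, 116118923 to 116158747, minus strand), the collagen of hypertrophic chondrocytes, rose 157-fold, from 11.02 ± 2.5 CPM (SD, n = 4) to 1734 ± 891 CPM (SD, n = 5). MKI67 (ENSG00000148773; chromosome 10, 128096659 to 128126385, minus strand), which marks dividing cells, went from 195 ± 12.3 CPM (SD, n = 4) to 68.2 ± 9.14 CPM (SD, n = 5).

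In edgeR's quasi-likelihood test, 10284 of the 17838 genes changed between day 21 and day 45, 4836 of them upwards and 5448 downwards, and 1827 rose and 2694 fell by more than 2-fold. The split between rises and falls depended on the scale. On log2(TPM + 1) limma called 2147 higher and 8722 lower at day 45, and the median change over all genes tested was -0.34 in place of -0.05 with TMM. For day 30 against day 21 that median was -0.35 on the TPM scale and 0.02 with TMM. For day 45 against day 30 it was 0.01 and -0.04. Relative to these shifts no list of genes called by camera changed direction on the TPM scale. The edgeR adjusted p was 2.36e-07 for COL2A1, 1.95e-08 for ACAN, 1.48e-10 for COL10A1 and 7.19e-08 for MKI67.

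Of the 24 cartilage matrix genes, 14 rose, 7 fell and 3 did not pass between day 21 and day 45 (camera adjusted p = 0.00523; adjusted p = 0.396 with an estimated correlation). COMP, a matrix protein that binds collagen, rose from 78.2 ± 10.2 CPM (SD, n = 4) to 2442 ± 799 CPM (SD, n = 5). PRELP, a leucine-rich proteoglycan, rose by a log2 fold change of 2.30 ± 0.15 (SE), MATN3, a matrilin, by 2.71 ± 0.19 (SE) and SNORC, a small proteoglycan of cartilage, by 2.60 ± 0.18 (SE). With limma voom and sample weights the call of this list ended (adjusted p = 0.0527). Among 12 transcription factors of chondrocytes 6 rose and none fell, and the list was not called (camera adjusted p = 0.0543). SOX9, the master regulator of the chondrocyte lineage, rose from 382 ± 45.5 CPM (SD, n = 4) to 662 ± 34 CPM (SD, n = 5). SOX8, a close relative, rose by 1.16 ± 0.10 (SE). SOX9 was not called by limma on log2(TPM + 1) (0.35, adjusted p = 0.0822), a scale on which the median of all genes was -0.34. Relative to that median its change was 0.69, against 0.85 with TMM.

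Hypertrophic cartilage genes rose in 13 of 16 members tested, 2 fell and 1 did not pass (camera adjusted p = 1e-09; adjusted p = 0.0541 with an estimated correlation). IHH (ENSG00000163501; chromosome 2, 219054420 to 219060467, minus strand), a signal made by prehypertrophic chondrocytes, rose from 1.28 ± 0.839 CPM (SD, n = 4) to 71.6 ± 19.6 CPM (SD, n = 5). TGM2, a protein-crosslinking transglutaminase, rose by 3.95 ± 0.16 (SE), the transcription factor gene FOXA2 by 5.42 ± 0.22 (SE) and PTH1R, the receptor of parathyroid hormone-related protein, by 4.08 ± 0.27 (SE). The 2 members that fell were RUNX2, a regulator of hypertrophy and bone formation (log2 fold change -0.51 ± 0.16, SE), and SPP1, which encodes osteopontin (-2.05 ± 0.48, SE). MMP13, a collagenase of late hypertrophic cartilage, rose from 42.8 ± 15.5 CPM (SD, n = 4) to 65.5 ± 15.5 CPM (SD, n = 5) with an edgeR adjusted p of 0.0346. Its call ended without day 21 replicate 1 (adjusted p = 0.0972), day 21 replicate 2 (0.0839), day 45 replicate 1 (0.0955) or day 45 replicate 2 (0.0568), without the low-count filter (0.146), with the offset (0.059), without day 30 replicates 3 to 5 (0.105), and on log2(TPM + 1) (limma adjusted p = 0.423; 0.57 relative to the median of all genes, against 0.67 with TMM). It also ended with day 45 replicate 1 placed at day 30 (0.202), with only these days fitted (0.0792) and against a 1.5-fold change (0.509). IBSP, which encodes bone sialoprotein, did not pass the filter on low counts.

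Lists of bone matrix (3 rose, 3 fell and 5 did not pass) and of phosphate handling (4 rose, 3 fell and 2 did not pass) were not called (camera adjusted p = 0.673 and 0.306). SP7, a transcription factor of osteoblasts, rose by 3.61 ± 0.31 (SE), and ALPL, the tissue phosphatase of mineralisation, rose from 0.138 ± 0.0944 CPM (SD, n = 4) to 5.99 ± 4 CPM (SD, n = 5). Without day 21 replicate 2 the log2 fold change of ALPL was 5.97 in place of 5.38. PHOSPHO1, a phosphatase of matrix vesicles, rose by 4.96 ± 0.33 (SE), and DMP1, a mineral-binding matrix protein, went down by -2.51 ± 0.31 (SE). COL1A1, the main collagen of bone and fibrous tissue, was at 5244 ± 711 CPM (SD, n = 4) and 6725 ± 1230 CPM (SD, n = 5) and did not pass the test (edgeR adjusted p = 0.067). The bone list had a median of -0.23 and a mean of 0.33.

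Genes for building and secreting the matrix rose as well. Of 23 genes of sulphated glycosaminoglycan synthesis, 15 rose, 4 fell and 4 did not pass (camera adjusted p = 1.81e-04; adjusted p = 0.307 with an estimated correlation). They included CHST3, a chondroitin sulfotransferase (113 ± 12.3 CPM, SD, n = 4, to 710 ± 40 CPM, SD, n = 5), PAPSS2, which makes the sulphate donor (2.64 ± 0.19, SE), and the nucleotide sugar transporter gene SLC35D1 (2.31 ± 0.19, SE). Of 23 genes of collagen processing and secretion, 15 rose, 2 fell and 6 did not pass (camera adjusted p = 9.15e-04; adjusted p = 0.295 with an estimated correlation). P4HA2, a subunit of collagen prolyl hydroxylase, rose by 2.39 ± 0.12 (SE), the procollagen protease gene ADAMTS2 by 2.90 ± 0.23 (SE) and LOX, which crosslinks collagen, by 1.91 ± 0.19 (SE). Of 16 matrix proteases 7 rose, 8 fell and 1 did not pass, and the list was not called (camera adjusted p = 0.315). MMP2, a gelatinase, went down by -2.16 ± 0.14 (SE) and HTRA1, a serine protease, by -1.69 ± 0.13 (SE).

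Cell cycle genes fell in all 22 members (camera adjusted p = 1.06e-08; adjusted p = 0.261 with an estimated correlation). CENPF, a kinetochore protein, dropped by 2.14 ± 0.13 (SE), CCNB1, the mitotic cyclin B1, by 1.73 ± 0.15 (SE) and BUB1, a spindle checkpoint kinase, by 1.42 ± 0.13 (SE). Hypoxia and glycolysis genes rose in 17 of 18 members, and 1 did not pass (camera adjusted p = 1e-09; adjusted p = 0.205 with an estimated correlation). ADM, which encodes adrenomedullin, rose by 5.94 ± 0.43 (SE), the stress gene NDRG1 by 2.25 ± 0.18 (SE) and the glycolytic genes ALDOC and PGK1 by 2.42 ± 0.19 and 1.47 ± 0.12 (SE). Without day 21 replicate 1 the change of ADM was 6.77. Cholesterol synthesis genes rose in 14 of 18 members, 1 fell and 3 did not pass (camera adjusted p = 0.00216; adjusted p = 0.317 with an estimated correlation), among them DHCR7, the last enzyme of one route to cholesterol (1.41 ± 0.12, SE), and MVD, an enzyme of the mevalonate pathway (1.05 ± 0.10, SE).

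Stress and signalling genes changed between the same days, and immediate early genes, a list fixed in advance as a sign of handling, changed with them. Of 15 genes of the unfolded protein response 12 rose, 1 fell and 2 did not pass (camera adjusted p = 2.25e-06; adjusted p = 0.122 with an estimated correlation), led by the stress transcription factor gene DDIT3 (2.97 ± 0.17, SE) and by TRIB3, a pseudokinase induced by stress (3.19 ± 0.18, SE). Among 15 genes of the p53 response 8 rose, 3 fell and 4 did not pass (camera adjusted p = 0.00523; adjusted p = 0.122 with an estimated correlation), and CDKN1A, the cell cycle inhibitor p21, rose from 27.1 ± 0.366 CPM (SD, n = 4) to 159 ± 10.3 CPM (SD, n = 5). Immediate early genes rose in 9 of 13 members, 1 fell and 3 did not pass (camera adjusted p = 4.14e-07; adjusted p = 0.122 with an estimated correlation), with DUSP1, a phosphatase of MAP kinases, at 2.69 ± 0.14 (SE) and the transcription factor gene FOS at 2.79 ± 0.16 (SE). Targets of TGF-beta rose in 7 of 10 members, 1 fell and 2 did not pass (camera adjusted p = 6.29e-04; adjusted p = 0.122 with an estimated correlation). CCN2, a connective tissue growth factor, rose by 3.57 ± 0.25 (SE). Targets of BMP rose in 8 of 10 members, 1 fell and 1 did not pass (camera adjusted p = 0.00379; adjusted p = 0.307 with an estimated correlation), with the inhibitor of differentiation ID2 at 1.85 ± 0.11 (SE). With day 45 replicate 1 placed at day 30 the call of the p53 list ended (camera adjusted p = 0.0512).

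Interferon response genes fell in 11 of 14 members, 1 rose and 2 did not pass (camera adjusted p = 0.00216; adjusted p = 0.122 with an estimated correlation). Summed over the members tested, this list was at 104 ± 14.3 CPM (SD, n = 4) at day 21 and 92.1 ± 9.34 CPM (SD, n = 5) at day 45. IFI44L and ISG15, both induced by interferon, were at 3.45 ± 0.962 and 4.42 ± 1.02 CPM (SD, n = 4) at day 21 and at 0.256 ± 0.133 and 1.08 ± 0.106 CPM (SD, n = 5) at day 45. Inflammatory cytokine response genes rose in 5 of 10 members, 1 fell and 4 did not pass (camera adjusted p = 0.0455; adjusted p = 0.261 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 2.26 ± 0.26 (SE), and SOD2, the mitochondrial superoxide dismutase, by 1.18 ± 0.12 (SE). The call of this list ended when any 1 of 8 libraries was left out (camera adjusted p = 0.0502 to 0.0764), namely day 21 replicates 2 and 4, day 30 replicates 2 and 3, and day 45 replicates 1, 2, 4 and 5. Without any 1 of the last 4 the median was 0.06 to 0.12 in place of 0.63. It was 0.32 without day 21 replicate 2 and 0.38 without day 21 replicate 4, and stayed at 0.63 without day 30 replicate 2 or 3. Without day 45 replicate 1, 9 members passed the filter. The call also ended with the length and GC offset (0.0523), without day 30 replicates 3 to 5 (0.0603), with limma voom (0.0715) and with day 45 replicate 1 placed at day 30 (0.162). Lists of WNT targets (2 rose, 4 fell, 3 did not pass) and of the Hedgehog pathway (2 rose, 5 fell, 2 did not pass) were not called (camera adjusted p = 0.276 and 0.568). DKK1, a WNT inhibitor, rose by 3.39 ± 0.24 (SE), and the Hedgehog receptor gene PTCH1 rose by 1.98 ± 0.28 (SE) while the Hedgehog-induced factor GLI1 went down by -1.58 ± 0.21 (SE). Of 22 ribosomal protein genes, many of which have near-identical copies, 9 rose and 13 did not pass, and the list was not called (camera adjusted p = 0.0825).

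Markers of other cell types mostly fell or were not called. Of 7 tendon genes 5 fell and 2 did not pass (camera adjusted p = 0.00475, or 0.122 with an estimated correlation), among them the tendon transcription factor gene SCX (39.6 ± 5.12 CPM, SD, n = 4, to 3.6 ± 0.515 CPM, SD, n = 5) and TNC, the matrix protein tenascin C (-2.80 ± 0.21, SE). Summed over the 7 genes, the level was 9160 ± 276 CPM (SD, n = 4) at day 21 and 8160 ± 372 CPM (SD, n = 5) at day 45. All 3 pluripotency genes tested fell (camera adjusted p = 0.00492; adjusted p = 0.122 with an estimated correlation), and DPPA4, the most abundant of them, went from 14.4 ± 1.81 CPM (SD, n = 4) to 0.578 ± 0.324 CPM (SD, n = 5). Of 7 neuronal genes 5 fell, 1 rose and 1 did not pass (camera adjusted p = 0.0491; adjusted p = 0.205 with an estimated correlation), with DCX, a microtubule protein of young neurons, at -4.42 ± 0.32 (SE). That call ended without any 1 of day 21 replicate 2, day 30 replicates 2, 3 and 4 and day 45 replicates 1, 2 and 4 (camera adjusted p = 0.0502 to 0.0644), without the low-count filter (0.0524) and with limma voom (0.0527). The lists of superficial zone and joint (7 rose, 2 fell, 3 did not pass; adjusted p = 0.0745), adipocytes (3, 0 and 3; 0.08), fibrous tissue (3, 7 and 6; 0.232), Schwann cells (3, 4 and 0; 0.232), melanocytes (2, 0 and 1; 0.232), skeletal muscle (2, 2 and 0; 0.264), endothelium (2, 1 and 0; 0.528), epithelium (3, 2 and 1; 0.648) and smooth muscle (3, 3 and 4; 0.878) were not called by camera. PRG4, the lubricin of the joint surface, rose by 0.87 ± 0.22 (SE). It was not called on log2(TPM + 1) (0.36, limma adjusted p = 0.203), where its change relative to the median of all genes was 0.70, against 0.93 with TMM. Cardiac muscle, blood and liver lists had fewer than 3 members tested. CD68, a lysosomal protein of macrophages and other cells, rose by 5.64 ± 0.26 (SE), and the other blood gene tested fell. The cardiac gene ACTN2 went down by -1.52 ± 0.38 (SE) and the liver factor FOXA1 by -2.88 ± 0.69 (SE), both at low levels. FOXA1, the only liver gene tested, was at a mean of 0.658 CPM at day 21 and 0.0827 CPM at day 45. The 2 cardiac genes tested together were at 2.22 and 0.686 CPM. Relative to the median of all genes, ACTN2, FOXA1 and DCX were at -0.41, -0.21 and -0.79 on log2(TPM + 1), against -1.47, -2.83 and -4.37 with TMM. On log2(TPM + 0.1), where that median was -0.46, FOXA1 and DCX were at -2.01 and -3.11 before taking it off. Without day 45 replicate 3 the change of FOXA1 was -3.62.

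Among genes with a mean of at least 10 CPM in the higher group and no overlap between the days, the largest rises included several that were close to absent at day 21. SLC27A2, a fatty acid transporter, had 4 counts over the day 21 libraries and 1972 at day 45, a ratio of 576 (counting interval 225 to 2120). CHI3L2, a chitinase-like secreted protein, went from 14 to 5898 counts (ratio 492, interval 293 to 901), PLA2G2A, a secreted phospholipase, from 7 to 1397 (ratio 233, interval 113 to 581) and MMP3, stromelysin, from 15 to 1335 (ratio 104, interval 62.8 to 186). HSPA6, a heat shock gene with near-identical copies, went from 3 to 2274 counts (ratio 885, interval 303 to 4300). Intervals cover counting error only. ABI3BP, an extracellular matrix protein, rose 117-fold and CRYAB, the small heat shock protein alpha B crystallin, 99.4-fold, from 6.72 ± 2.19 CPM (SD, n = 4) to 669 ± 74.5 CPM (SD, n = 5). Among the largest falls, GRP, a neuropeptide, went from 1568 to 4 counts (336 times lower, interval 131 to 1230) and the synaptic organiser CBLN2 from 5602 to 20 (240 times lower, interval 155 to 393). MMP9, the gelatinase of osteoclasts and other cells (ENSG00000100985; chromosome 20, 46008908 to 46016561, plus strand), went from 175 ± 26.8 CPM (SD, n = 4) to 0.593 ± 0.787 CPM (SD, n = 5). FSTL5, TRIL, CNTNAP2, COL22A1 and LYPD1 went down by log2 fold changes of -7.04, -6.07, -5.72, -5.51 and -5.49, each with an SE of 0.21 to 0.48. Without day 45 replicate 2 the change was -9.45 in place of -8.16 for MMP9 and -6.69 for LYPD1, and without day 45 replicate 4 it was -8.79 in place of -8.20 for GRP. Without day 21 replicate 1 it was 8.46 in place of 7.73 for PLA2G2A and 10.38 in place of 9.51 for HSPA6. Relative to the median of all genes, HSPA6, SLC27A2, CHI3L2 and MMP3 were at 4, 3.71, 6.02 and 3.67 on log2(TPM + 1), against 9.56, 9, 8.93 and 6.69 with TMM. Among the falls, GRP, CBLN2, MMP9 and FSTL5 were at -4.71, -4.84, -6.62 and -3.64, against -8.15, -7.82, -8.11 and -6.98. TRIL, CNTNAP2, COL22A1 and LYPD1 were at -3.26, -3.84, -4.69 and -3.15, against -6.01, -5.66, -5.46 and -5.44. These values depended on the amount added to TPM. On log2(TPM + 0.1), where the median of all genes was -0.46, HSPA6, SLC27A2, CHI3L2 and MMP3 were at 6.66, 5.89, 7.2 and 5.71. On that scale CBLN2, MMP9 and FSTL5 were at -7.28, -8.83 and -6.45. The median was not taken off these values.

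Adjusted over the list alone, the calls of the 9 following lists differed by 1 member from those over all genes tested: cartilage matrix (14 higher, 8 lower), superficial zone (7 and 3), glycosaminoglycan synthesis (16 and 4), interferon response (1 and 12), immediate early genes (10 and 1), TGF-beta targets (8 and 1), WNT targets (3 and 4), Hedgehog pathway (3 and 5) and ribosomal proteins (8 and 0). Of the 33 lists with at least 3 members tested, camera called 17, 12 upwards and 5 downwards, with a preset correlation, and none with a correlation estimated per list.

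**Figure D3:**
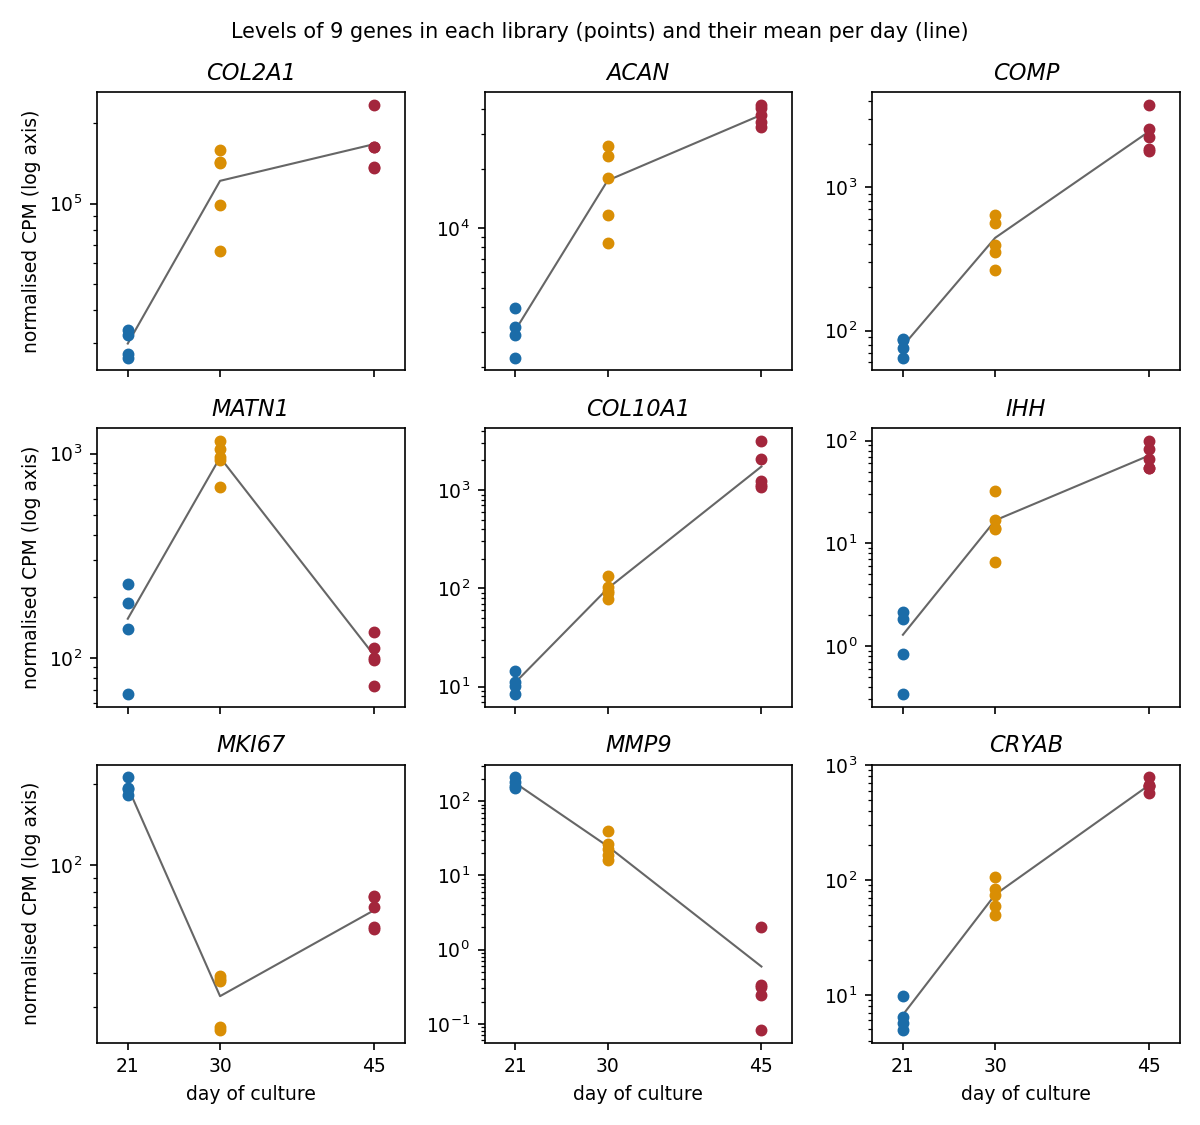
Normalised CPM (log axis) of 9 genes at day 21 (n = 4), day 30 (n = 5) and day 45 (n = 5), with 1 point per library and a line through the means. COL10A1 and CRYAB rise through all 3 days, MATN1 peaks at day 30 (957 CPM), MKI67 is lowest at day 30 (32.8 CPM) and MMP9 falls to 0.593 CPM.

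Between day 21 and day 30, 22 of 24 cartilage matrix genes rose and all 22 cell cycle genes fell (camera adjusted p = 1.08e-11 and 6.09e-23; adjusted p = 0.197 for each with an estimated correlation). COL2A1 rose 4.07-fold to 121800 ± 37900 CPM (SD, n = 5) and ACAN 5.69-fold to 17410 ± 7380 CPM (SD, n = 5). COL10A1 was already 9.02-fold higher, at 99.4 ± 20.8 CPM (SD, n = 5), and IHH 12.8-fold, at 16.7 ± 9.56 CPM (SD, n = 5). With day 45 replicate 1 placed at day 30, as its treatment label reads, the log2 fold change was 5.79 in place of 3.17 for COL10A1 and 4.56 in place of 3.68 for IHH. MKI67 went down by -2.57 ± 0.15 (SE), to 32.8 ± 7.31 CPM (SD, n = 5). SOX9 rose by 0.66 ± 0.14 (SE) and PRG4 by 1.54 ± 0.22 (SE), while RUNX2 (0.17 ± 0.16, SE), MMP13 (0.08 ± 0.23, SE), SPP1 (-1.15 ± 0.47, SE) and COL1A1 (0.35 ± 0.16, SE) did not pass the test. SOX9 was not called by limma on log2(TPM + 1) (0.18, adjusted p = 0.382), where the median of all genes was -0.35. Relative to that median its change was 0.52, against 0.64 with TMM.

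Of 24 cartilage matrix genes 22 rose and 2 fell from day 21 to day 30 (camera adjusted p = 1.08e-11; adjusted p = 0.197 with an estimated correlation). CHAD, a matrix protein that binds cells, rose from 49.4 ± 15.8 CPM (SD, n = 4) to 443 ± 101 CPM (SD, n = 5), HAPLN1, the link protein of aggrecan, by 2.10 ± 0.20 (SE), SNORC by 2.44 ± 0.18 (SE) and MATN3 by 2.03 ± 0.18 (SE). Hypertrophic cartilage genes rose in 12 of 16 members and 4 did not pass (camera adjusted p = 6.32e-09; adjusted p = 0.0982 with an estimated correlation), with FOXA2 at 4.07 ± 0.22 (SE), S100A1, a calcium-binding protein, at 2.63 ± 0.19 (SE) and SCIN, the actin-severing protein scinderin, at 2.14 ± 0.16 (SE). Glycosaminoglycan synthesis genes rose in 15 of 23 members, 4 fell and 4 did not pass (camera adjusted p = 0.00269; adjusted p = 0.539 with an estimated correlation), and collagen processing genes rose in 13 of 23, 1 fell and 9 did not pass (camera adjusted p = 0.00846; adjusted p = 0.539 with an estimated correlation). PAPSS2 rose by 1.96 ± 0.18 (SE) and P4HA2 by 1.32 ± 0.12 (SE).

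All 22 cell cycle genes fell by day 30 (camera adjusted p = 6.09e-23; adjusted p = 0.197 with an estimated correlation), and CENPF, BUB1 and TOP2A, the DNA topoisomerase of dividing cells, went down by -2.70 ± 0.13, -1.99 ± 0.14 and -2.46 ± 0.17 (SE). Hypoxia and glycolysis genes rose in 16 of 18 members and 2 did not pass (camera adjusted p = 9.49e-08; adjusted p = 0.364 with an estimated correlation). BNIP3, a mitophagy receptor, rose by 2.54 ± 0.27 (SE), and ADM by 3.83 ± 0.42 (SE), or 4.66 without day 21 replicate 1 and 4.62 with day 45 replicate 1 placed at day 30. Unfolded protein response genes rose in 8 of 15 members, 2 fell and 5 did not pass (camera adjusted p = 0.00134; adjusted p = 0.288 with an estimated correlation), with DDIT3 at 2.66 ± 0.17 (SE) and ASNS, the asparagine synthetase, at 1.56 ± 0.13 (SE). Interferon response genes fell in 10 of 14 members, 1 rose and 3 did not pass (camera adjusted p = 0.00747, or 0.288 with an estimated correlation), with IFIT3, an interferon-induced protein, at -2.08 ± 0.23 (SE). Summed over the members tested, the list was at 104 ± 14.3 CPM (SD, n = 4) at day 21 and 81.1 ± 10.8 CPM (SD, n = 5) at day 30. BMP targets rose in 7 of 10 members and 3 fell (camera adjusted p = 0.0307; adjusted p = 0.539 with an estimated correlation); NOG, a secreted BMP inhibitor, rose by 2.11 ± 0.16 (SE) and the inhibitory SMAD7 went down by -0.64 ± 0.08 (SE). That call ended with the length and GC offset (adjusted p = 0.269), with limma voom (0.0594) and without day 21 replicate 2 (0.0526).

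The 3 pluripotency genes fell (camera adjusted p = 0.0393; adjusted p = 0.297 with an estimated correlation), and DPPA4 went down by -1.74 ± 0.23 (SE). This call ended without day 30 replicate 1 (adjusted p = 0.0582), without replicate 2 (0.0562), without replicates 3 to 5 (0.0539), with the offset (0.0641), without the low-count filter (0.116) and with limma voom (0.0642). Ribosomal protein genes rose in 21 of 22 members and 1 did not pass (camera adjusted p = 0.00104; adjusted p = 0.633 with an estimated correlation). They have short transcripts, but the list kept its call with the length and GC offset. Without day 30 replicates 3 to 5 their median change was 0.18 in place of 0.6 and the list was not called (adjusted p = 0.146). RPS18, a protein of the small subunit with many pseudogenes, was at 1.05 ± 0.21 (SE) and at 0.40 without those libraries. No other list was called by camera in this comparison. The median, mean and test differed in sign for transcription factors of chondrocytes, smooth muscle, Schwann cells, endothelium, the p53 response, TGF-beta targets and the Hedgehog pathway.

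Among genes with a mean of at least 10 CPM in the higher group and no overlap between the days, the largest rises from day 21 to day 30 were those of ZNF385B, a zinc finger protein (63.9-fold), NDUFA4L2, a mitochondrial protein induced by low oxygen (35.6-fold), FGFBP2 (33.9-fold), DDIT4L, a relative of a stress-induced mTOR inhibitor (30.1-fold), FRZB, a secreted WNT antagonist of cartilage (23.4-fold), SERPINA1, alpha-1 antitrypsin (22.6-fold), and SMIM5 (20.5-fold). TRIM53AP, a pseudogene that shares sequence with its relatives and is uncertain for this reason, was 83.1-fold higher. The log2 fold change of SERPINA1 was 5.24 in place of 4.50 with day 45 replicate 1 placed at day 30. Relative to the median of all genes, TRIM53AP was at 4 on log2(TPM + 1), against 6.36 with TMM, and DDIT4L at 3 against 4.89. On log2(TPM + 0.1), where that median was -0.45, they were at 5.43 and 4.02 before taking it off. By the same rule, the largest falls were those of FRAS1, an extracellular matrix protein of basement membranes (-4.14 ± 0.31, SE), IQGAP2, a scaffold protein (-3.65 ± 0.18, SE), TMEM132B (-3.38 ± 0.20, SE), CBLN2 (-3.35 ± 0.22, SE), FSTL5 (-3.25 ± 0.23, SE), ETV4, a transcription factor downstream of FGF signalling (-3.18 ± 0.25, SE), NDST3, a heparan sulphate sulfotransferase (-3.16 ± 0.21, SE), and THSD7A (-3.13 ± 0.28, SE). On log2(TPM + 1), FRAS1, TMEM132B and THSD7A were at -1.83, -1.81 and -1.01 relative to the median, against -4.16, -3.4 and -3.15 with TMM. IQGAP2, CBLN2, FSTL5, ETV4 and NDST3 moved less, to -2.7, -3.13, -2.7, -2.92 and -2.15. Among the falls too the amount added mattered, as FSTL5 and ETV4 were at -3.84 and -3.79 on log2(TPM + 0.1).

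In edgeR's test 9696 genes changed from day 21 to day 30, 4858 upwards and 4838 downwards, with 1837 and 1814 of them by more than 2-fold. On log2(TPM + 1) limma called 1788 higher and 9019 lower. Camera called 11 of 33 lists, 8 upwards and 3 downwards, and none with a correlation estimated per list. Adjusted over the list alone, the calls were the same in number except for hypertrophic cartilage (13 higher, 1 lower), bone matrix (4 and 4), phosphate handling (4 and 4) and neurons (1 and 5). Without day 30 replicates 3 to 5, edgeR called 7645 genes.

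**Figure D4:**
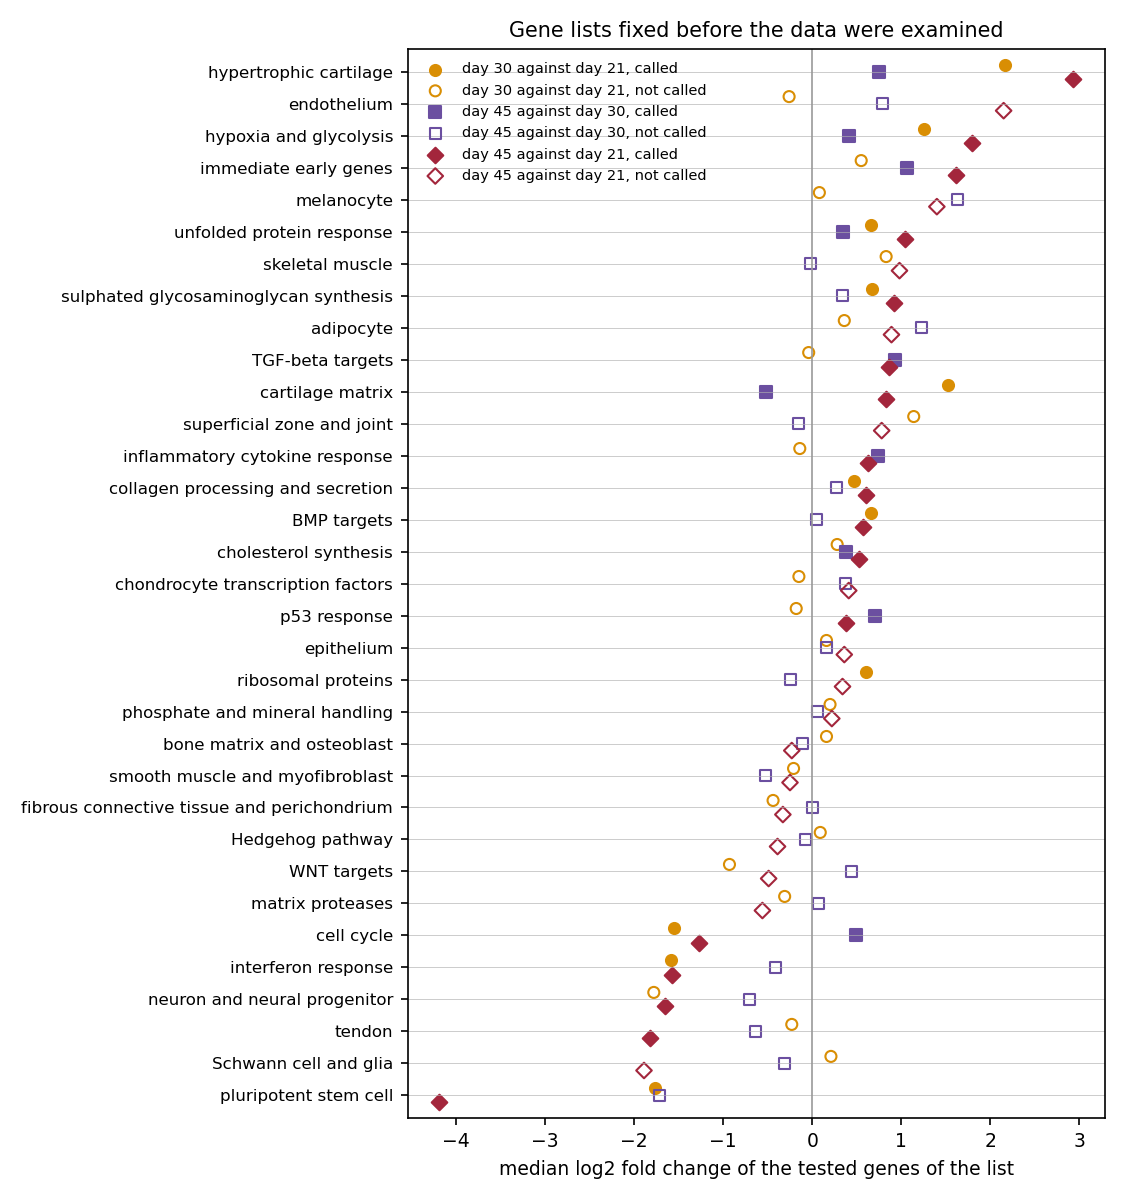
Median log2 fold change of the tested members of each of 33 gene lists in the 3 comparisons of days, with filled points for lists called by camera at a preset correlation and open points for the others. Camera called 17 lists for day 45 against day 21, 11 for day 30 against day 21 and 10 for day 45 against day 30, and none with an estimated correlation; the cell cycle list lies at -1.27, -1.55 and 0.49.

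From day 30 to day 45, 10 of 16 hypertrophic cartilage genes rose and 12 of 24 cartilage matrix genes fell (camera adjusted p = 0.0148 and 0.00313; adjusted p = 0.516 and 0.645 with an estimated correlation). COL10A1 rose 17.4-fold (log2 fold change 4.12 ± 0.30, SE), IHH 4.32-fold (2.11 ± 0.39, SE) and ACAN 2.14-fold (1.10 ± 0.25, SE). These calls ended with day 45 replicate 1 placed at day 30 (edgeR adjusted p = 0.334, 0.152 and 0.0865). They stayed with that library left out. It lay at 44.2 on the first component, with the day 30 libraries at -9 to 0.4. COL2A1 did not pass the test (0.46 ± 0.22, SE, edgeR adjusted p = 0.0889), nor did SOX9 (0.13 ± 0.13, SE), SPP1 (-0.90 ± 0.45, SE) or COL1A1 (0.01 ± 0.15, SE). UCMA, a secreted protein of the resting and upper growth plate (ENSG00000165623; chromosome 10, 13221767 to 13234334, minus strand), went from 153 ± 33 CPM (SD, n = 5) to 3.42 ± 1.39 CPM (SD, n = 5). MATN1, a matrilin of cartilage, went from 957 ± 174 CPM (SD, n = 5) to 104 ± 22.3 CPM (SD, n = 5).

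Of the 24 cartilage matrix genes 5 rose, 12 fell and 7 did not pass from day 30 to day 45 (camera adjusted p = 0.00313; adjusted p = 0.645 with an estimated correlation). Besides UCMA and MATN1, EPYC, a small proteoglycan (-2.04 ± 0.15, SE), MIA, a secreted cartilage protein (-1.76 ± 0.14, SE), and CNMD, the angiogenesis inhibitor chondromodulin (-1.95 ± 0.16, SE), fell. COMP rose by 2.46 ± 0.24 (SE) and PRELP by 1.08 ± 0.13 (SE). Summed over the 24 genes, the level was not lower, at 210000 ± 62800 CPM (SD, n = 5) at day 30 and 258000 ± 50000 CPM (SD, n = 5) at day 45. With limma voom the call of the list ended (adjusted p = 0.0542). Hypertrophic cartilage genes rose in 10 of 16 members, 2 fell and 4 did not pass (camera adjusted p = 0.0148; adjusted p = 0.516 with an estimated correlation), with TGM2 at 1.91 ± 0.13 (SE) and RUNX2 at -0.68 ± 0.15 (SE). S100A1 was the other member that fell. Without day 30 replicates 3 to 5 this list was not called (adjusted p = 0.0845). PRG4 went down by -0.66 ± 0.20 (SE), and MMP13 rose by 0.54 ± 0.22 (SE, edgeR adjusted p = 0.0484). The MMP13 call ended without any 1 of day 21 replicate 2, day 30 replicates 2, 4 and 5, and day 45 replicates 1, 2 and 4 (log2 fold change 0.39 to 0.55, edgeR adjusted p = 0.057 to 0.141). It also ended under both other filters (0.133 and 0.054), with the replicate block (0.0657), the offset (0.0927), thinning (0.0587) and limma voom (0.0511), against a 1.5-fold change (0.733), and without day 30 replicates 3 to 5 (0.287). The PRG4 call ended without the low-count filter (adjusted p = 0.0602).

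Cell cycle genes rose in 13 of 22 members and 9 did not pass (camera adjusted p = 0.00471; adjusted p = 0.685 with an estimated correlation). MKI67 rose by 1.05 ± 0.14 (SE), to 68.2 ± 9.14 CPM (SD, n = 5), and the replication licensing genes MCM3, MCM6 and MCM4 rose by 0.70 ± 0.10, 0.56 ± 0.09 and 0.84 ± 0.13 (SE). TGF-beta targets rose in 9 of 10 members and 1 did not pass (camera adjusted p = 9.93e-05; adjusted p = 0.183 with an estimated correlation), with CCN2 at 1.91 ± 0.21 (SE) and LTBP2, a matrix protein of elastic fibres, at 1.33 ± 0.16 (SE). Immediate early genes, the list fixed as a sign of handling, rose over the same interval in 11 of 13 members and 2 did not pass (camera adjusted p = 9.9e-07; adjusted p = 0.232 with an estimated correlation), with DUSP1 at 2.09 ± 0.12 (SE) and JUN at 1.49 ± 0.10 (SE). The p53 response rose in 10 of 15 members, 1 fell and 4 did not pass (camera adjusted p = 3.62e-04; adjusted p = 0.119 with an estimated correlation), with CDKN1A at 1.46 ± 0.08 (SE) and TNFRSF10B, a death receptor, at 1.18 ± 0.10 (SE). Inflammatory genes rose in 6 of 10 members and 4 did not pass (camera adjusted p = 0.00655; adjusted p = 0.232 with an estimated correlation), with PTGS2 at 2.61 ± 0.25 (SE).

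Unfolded protein response genes rose in 6 of 15 members, 1 fell and 8 did not pass (camera adjusted p = 0.0198; adjusted p = 0.516 with an estimated correlation), with HSPA5, the chaperone BiP, at 0.87 ± 0.12 (SE). Hypoxia and glycolysis genes rose in 7 of 18 members and 11 did not pass (camera adjusted p = 0.0223; adjusted p = 0.740 with an estimated correlation), with NDRG1 at 1.53 ± 0.16 (SE). Cholesterol synthesis genes rose in 11 of 18 members and 7 did not pass (camera adjusted p = 0.0261; adjusted p = 0.685 with an estimated correlation), with DHCR7 at 0.67 ± 0.11 (SE). The cholesterol list lost its call without day 45 replicate 1 (adjusted p = 0.0506), and it and the hypoxia list lost theirs without day 30 replicates 3 to 5 (0.0815 for each). No other list was called by camera in this comparison. The median, mean and test differed in sign for the superficial zone, matrix protease and Hedgehog lists.

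By the same rule of at least 10 CPM and no overlap, the largest rises after day 30 were those of CHI3L2 (56.7-fold), MMP3 (29.5-fold), MMP7, matrilysin (20.7-fold), COL10A1, ABLIM3, an actin-binding protein (16.4-fold), ANPEP, a membrane aminopeptidase (16.1-fold), and FIBCD1, a chitin-binding receptor (15.6-fold); HSPA6 was 32.8-fold higher. Among the largest falls besides UCMA and MATN1 were those of MMP9 (-5.34 ± 0.48, SE; -6.62 without day 45 replicate 2), AQP6, an aquaporin (-3.95 ± 0.29, SE), and FBN3, a fibrillin of fetal tissues (-3.83 ± 0.17, SE). MTMR9LP (-3.38 ± 0.24, SE) and CLEC18C (-3.26 ± 0.31, SE) share sequence with near-identical copies and are uncertain.

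In edgeR's test 10051 genes changed from day 30 to day 45, 4930 upwards and 5121 downwards, and 1152 rose and 2430 fell by more than 2-fold. Camera called 10 of 33 lists, 9 upwards and 1 downwards, and none with a correlation estimated per list. Adjusted over the list alone, the calls were the same in number except for transcription factors of chondrocytes (10 higher, 1 lower), collagen processing (11 and 8), epithelium (0 and 0), cholesterol synthesis (12 and 0) and ribosomal proteins (0 and 5). Without day 30 replicates 3 to 5, edgeR called 7192 genes. With day 45 replicate 1 placed at day 30, as its treatment label reads, edgeR called 6466 genes and camera 4 lists. Among the genes given above for this comparison, that placement ended the calls of ACAN (log2 fold change 0.75), COL10A1 (1.18), IHH (1.08), CHI3L2 (1.5, adjusted p = 0.294), MMP3 (1.84, 0.134), MMP7 (1.62, 0.161), ANPEP (1.66, 0.144), FIBCD1 (1.43, 0.191), PTGS2 (1.24, 0.112), CCN2 (0.73, 0.252), LTBP2 (0.79, 0.0625), MCM4 (0.49, 0.0945) and MMP13 (0.17, 0.634). The calls of HSPA6 (2.42 in place of 5.04), ABLIM3 (2.12 in place of 4.04) and DUSP1 (1.22 in place of 2.09) stayed. It also ended the calls of the hypertrophic (adjusted p = 0.272), cell cycle (0.0752), hypoxia (0.0503), cholesterol (0.0752), inflammatory (0.0752) and TGF-beta (0.0502) lists. With that library left out instead, only MMP13 of these genes lost its call. Camera then still called the hypertrophic (adjusted p = 0.0111), cell cycle (0.0111), hypoxia (0.0306), inflammatory (0.0142) and TGF-beta (6.57e-06) lists but not the cholesterol list (0.0506).

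The test of whether the change from day 30 to day 45 differed from that from day 21 to day 30 asks for a different amount of change, not for a change of direction. MATN1 rose and then fell, with a difference of -5.83 ± 0.43 (SE) between its changes in the later and the earlier interval, and UCMA did the same, from 32.0 ± 9.89 CPM (SD, n = 4) to 153 ± 33 CPM (SD, n = 5) to 3.42 ± 1.39 CPM (SD, n = 5), with a difference of -7.75 ± 0.45 (SE). MKI67 fell and then rose (3.62 ± 0.26, SE). For COMP (-0.04 ± 0.40, SE, edgeR adjusted p = 0.938), COL10A1 (0.95 ± 0.48, SE, 0.104) and CRYAB (-0.31 ± 0.34, SE, 0.461) no difference between the intervals passed the test. For COL2A1 (-1.57 ± 0.38, SE) and ACAN (-1.41 ± 0.43, SE) the later change was the smaller.

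Among genes with a mean of at least 10 CPM at some day, the most negative differences after UCMA were those of TRIM53AP (-7.28 ± 0.55, SE), AQP6 (-6.55 ± 0.44, SE), FER1L4 (-6.25 ± 0.66, SE), a transcribed pseudogene, and CLEC18C (-6.07 ± 0.50, SE). The most positive were those of POMK, a kinase that modifies dystroglycan (4.70 ± 0.69, SE), PAPPA, a protease of IGF-binding proteins (4.03 ± 0.31, SE), CLSPN, a checkpoint protein of DNA replication (3.96 ± 0.28, SE), PTGR1, a prostaglandin reductase (3.90 ± 0.31, SE), and ATAD2, a chromatin protein of dividing cells (3.78 ± 0.26, SE). POMK was at 9.57 ± 1.39 CPM (SD, n = 4), 2.04 ± 1.7 CPM (SD, n = 5) and 11.5 ± 1.98 CPM (SD, n = 5). Its difference was 5.96 without day 30 replicate 1 and 2.92 without day 30 replicates 3 to 5. Without those replicates the differences of PTGR1, UCMA and TRIM53AP were 3.22, -7.04 and -8. The differences of POMK, PAPPA, CLSPN, PTGR1, ATAD2 and UCMA were 3.38, 2.73, 3.13, 2.26, 2.72 and -7.13 with day 45 replicate 1 placed at day 30. Those of PAPPA, ATAD2 and UCMA were 3.16, 3.14 and -6.92 with the length and GC offset.

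In edgeR's test the change differed between the intervals for 9404 genes, with 4505 positive and 4899 negative differences, of which 2764 and 3340 were more than 2-fold. On log2(TPM + 1) limma called 7354 positive and 2326 negative, with a median over all genes of 0.37 in place of -0.08. Without day 30 replicates 3 to 5 the count was 5659. The intervals last 9 and 15 days, and whole changes were compared, not rates.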

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

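No test in this part was chosen only after its result was seen, except the offset, leaving out day 30 replicates 3 to 5 and thinning.

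Within a day, 1 library lay far from the others in 21 of 447 groups of values examined, by the gap to its nearest neighbour as a share of the whole range (Dixon's ratio). Chance gives about 1 in 20 such groups. Day 45 replicate 1, the library with conflicting labels, was high in COL2A1 (ratio 0.723; 235000 CPM against 136000 to 164000 in the other day 45 libraries; share of counts 17.8% against 12% to 13.6%, ratio 0.724), SPP1 (0.755; 35.1 against 9.6 to 15.8) and DKK1 (0.825; 15.5 against 9.01 to 10.1), and low in ASNS (0.832; 79 against 100 to 105). Day 45 replicate 2 was high in MMP9 (0.87; 1.99 against 0.0823 to 0.331 CPM), LYPD1 (0.809; 1.39 against 0.0785 to 0.329), IFI44L (0.74; 0.488 against 0.147 to 0.236), TNC (0.737; 134 against 55 to 75.8) and NDUFA4L2 (0.808; 272 against 185 to 202), and day 45 replicate 5 was low in AQP6 (0.853; 0.206 against 0.751 to 0.845).

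Among the day 30 libraries, replicate 1 was high in PTGS2 (ratio 0.773; 10.8 against 5.7 to 6.86 CPM), replicate 2 in PHOSPHO1 (0.754; 17.9 against 5.23 to 8.34) and replicate 5 in IQGAP2 (0.771; 7.04 against 3.77 to 4.52), while replicate 3 was low in ASNS (0.82; 109 against 127 to 131). Among the day 21 libraries, replicate 1 was high in FRAS1 (0.84; 41.9 against 29.2 to 31.3 CPM), and replicate 2 was high in ALPL (0.897; 0.279 against 0.0834 to 0.103) and SP7 (0.845; 1.24 against 0.595 to 0.695) and low in TRIL (0.908; 24.1 against 31.7 to 32.5). Replicate 3 was low in SOX8 (0.885; 59.8 against 68.6 to 69.7) and UCMA (0.83; 17.3 against 34.7 to 38.2).

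Other splits of the libraries were drawn to ask whether chance can give as many genes. For day 30 against day 21, 1 of 100 splits, the real one, gave as many genes (9696 called by edgeR), and the highest other gave 8048. That split set the 4 day 21 libraries with day 30 replicate 1 against the other 4 day 30 libraries, and so follows the days except for 1 library. For day 45 against day 30, 1 of 100 splits, the real one, gave 10051 and the highest other gave 1. For day 45 against day 21, 1 of 100, the real one, gave 10284 and the highest other 7024, with the 4 day 21 libraries and day 45 replicate 4 against the rest. A chance division of these libraries is an unlikely source of these counts, and the median of the other splits was 0. The labels do not say whether replicates are separate cultures. If they are not, these splits cannot tell a difference between days from a chance difference between cultures.

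The number of genes whose change differed between the intervals was 9404. Of 100 splits, 1, the real one, gave as many, and the highest other gave 7549, with all 5 day 45 libraries in the middle place, which points to the structure of the samples. With the length and GC offset edgeR called 9483 genes. A trend with transcript length or GC content therefore cannot be the whole cause of that count. The genes called need not be the same, since 84.4% of all genes tested kept the sign of their difference with the offset, after taking off the median. With all libraries thinned to the smallest total edgeR called 8954, so lower depth at day 30 cannot be the whole cause either. Without day 30 replicates 3 to 5 it called 5659, with fewer samples. A change of course of many genes around day 30 stays open as a hypothesis, as does a difference in how the libraries of each day were prepared, for which the labels give no batch.

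Cell cycle genes were lowest at day 30. With the offset their median change from day 30 to day 45 was 0.46 (camera adjusted p = 0.00525), and without day 30 replicates 3 to 5 it was 0.68 (3.31e-07), against 0.49 with neither, so neither the trend nor those libraries alone can be the whole cause. Their median change from day 21 to day 30 was -1.55, while the middle 95% of 10000 random lists matched on abundance lay between -0.32 and 0.23 and 0 were as low. Such lists do not hold the correlation between cell cycle genes, and with an estimated correlation camera called neither the fall (adjusted p = 0.197) nor the later rise (0.685). Less division at day 30 than at day 21 is a hypothesis that these tests leave open. With day 45 replicate 1 placed at day 30 the median later change was 0.26 and the list was not called (camera adjusted p = 0.0752), while with that library left out it was 0.40 and the list was called (0.0111). The values of this library argue against that placement: it lay at 44.2 on the first component, with day 30 at -9 to 0.4, and COL10A1 made up 0.239% of its counts, against 0.00789% to 0.0122% at day 30. With the library placed there the pseudo-F was 11.2 in place of 20.3.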

How the results depend on the processing

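The length and GC offset, the fit without day 30 replicates 3 to 5 and thinning were tests chosen only after the results were seen. The counts of genes changed stayed within 1.5 times those reported under DESeq2 and its size factors, both other filters, voom, dispersions without robust fitting, fits of only the days compared, the offset and thinning. With 1 library left out in turn, they ranged from 8768 to 9938 for day 30 against day 21 (higher 4345 to 4917, lower 4423 to 5021), 9031 to 10235 for day 45 against day 30 (4521 to 5023, 4387 to 5212), 9335 to 10460 for day 45 against day 21 (4373 to 4933, 4962 to 5527) and 8262 to 9623 for the second interval (4004 to 4644, 4149 to 4979). Lists called ranged from 10 to 13, 9 to 13 and 15 to 20 in the same order of days, and the pseudo-F from 16.6 to 21.5. With the replicate numbers as a block, which do not pair the samples, 8872, 9519, 9728 and 8632 genes were called. With day 45 replicate 1 placed at day 30, edgeR called 6466 genes (higher 3036) and camera 4 lists for day 45 against day 30, and the pseudo-F was 11.2. The values of that library argue against this placement, since it lay at 44.2 on the first component, with day 30 at -9 to 0.4. How much of the lower counts comes from mixing unlike libraries was not tested. Without day 30 replicates 3 to 5 the second interval had 5659 genes (higher 2848, lower 2811), with fewer samples by construction; the cause was not tested. A test against a 1.5-fold change asks for more by construction and called 3705 (higher 1751, lower 1954), 3523 (1374, 2149), 4769 (2090, 2679) and 5782 (2694, 3088) genes. On log2(TPM + 1) limma called 1788 higher and 9019 lower for day 30 against day 21, 2147 and 8722 for day 45 against day 21, and 7354 and 2326 for the second interval. On log2(TPM + 0.1) these were 1750 and 8886, 2124 and 8646, and 7086 and 2353. The cause of these splits was not tested. With an estimated correlation camera called 0 lists in each comparison of days (5, 4 and 8 of 33 at an unadjusted p under 0.05, for day 30 against day 21, day 45 against day 30 and day 45 against day 21), while fry, which tests each list against no change and not against the other genes, called 23, 23 and 29. Summed over the comparisons, and over named genes that include more than those given in the text, 47 calls ended with day 45 replicate 1 placed at day 30, 22 without day 30 replicates 3 to 5, 8 with the offset and 35 on log2(TPM + 1). Thinned to the smallest library, edgeR called 9270, 9392, 9597 and 8954 genes.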

Other observations

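The groups of genes in these paragraphs were chosen after their values were seen. No test in this part was made to separate explanations.

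The pellets held almost no HOX transcripts, while several position genes of the head mesenchyme were present. All 39 HOX genes together had 2 to 33 counts per library, the highest single gene had 7, 13 had none, and 0 passed the filter. Of 13 other position genes, all tested, 12 were lower at day 45 than at day 21 in edgeR's test and FOXC1 was not called. DLX1 was at 33.8, 25.1 and 14.5 CPM at days 21, 30 and 45, MSX2 at 63.4, 35.1 and 32.2 and LMX1B at 43.4, 16.7 and 14.1.

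Chaperone genes and metallothioneins rose between day 30 and day 45, and some of them before. Of 10 small heat shock protein and chaperone genes, 5 rose and 1 fell from day 21 to day 30 and 10 rose from day 30 to day 45 in edgeR's test. HSPB1 was at 165, 180 and 413 CPM, and BAG3, a partner of HSP70, at 27.1, 52 and 112. Of 3 metallothioneins tested, 2 rose from day 21 to day 30 and all 3 from day 30 to day 45, with MT2A at 21.2, 20.7 and 115 CPM. Immediate early genes, a list fixed in advance as a sign of handling, rose over that interval too, in 11 of 13 members (camera adjusted p = 9.9e-07; adjusted p = 0.232 with an estimated correlation). Of 5 imprinted growth genes tested, all 5 rose from day 21 to day 30. From day 30 to day 45 IGF2, H19 and CDKN1C rose, DLK1 fell and PLAGL1 did not pass. IGF2 and H19, which share a locus, were at 1680, 3760 and 5740 CPM and at 1640, 3780 and 6010 CPM. DLK1 was at 1220, 2380 and 1240 CPM, and the imprinted MEG3 of the same locus had 0 to 8 counts per library.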
